A study of Arabidopsis thaliana with 4 samples.

How the data were processed

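Small RNAs were measured in shoot apices of 4-week-old Arabidopsis thaliana plants that carry pUBI10:mCherry-GR-linker-WUS. This transgene drives, from a ubiquitin promoter, the homeodomain transcription factor WUSCHEL (WUS) fused to mCherry and to the hormone-binding part of the glucocorticoid receptor (GR), which keeps a fused protein out of the nucleus until the steroid dexamethasone (DEX) is given. Per the labels, plants grew in soil in a greenhouse at 22 °C with 16 h light and 8 h dark, received 15 µM DEX or a mock treatment, and were sampled at day 2. Older flowers had been removed from the apices. There were 2 biological replicates per group and 4 libraries, and every library was used. The series holds no DEX-treated plants without the transgene, so DEX and WUS induction were not separated by the design.

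RNA was extracted with the mirVana kit, size-selected on a gel, made into libraries with the NEXTflex Small RNA kit and sequenced on a HiSeq2000. The extraction protocol gives the gel range as 10 to 60 nt, whereas the series design gives 18 to 60 nt, and which of them was used is not known. The deposited files hold sequences of 16 to 50 nt. The counts deposited by the authors are the number of reads of each distinct sequence in each library, with no normalization. The other deposited column is the length of the sequence in nt, and it equalled the number of letters in each line. CASAVA 1.4 and the TAIR10 build are named in the submitters' processing notes, and the aligner is not given in the sources used here. The files still hold reads that do not match the genome.

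The total number of reads per library was 10015234 and 10277955 in mock replicates 1 and 2, and 10048885 and 11171446 in DEX replicates 1 and 2. These came from 3372903, 3323354, 2935248 and 3366576 distinct sequences in the same order, and reads of sequences seen once were 24.8%, 23.7%, 21.5% and 22.2% of the totals. Reads with an undetermined base (68, 63, 57 and 57) were left out of the placement. A count of 0 allows up to 0.300, 0.292, 0.299 and 0.269 reads-per-million (RPM, of the total reads of the library) at 3 counts. A fold against a group with no reads is given as a lower bound, at 3 counts over the reads of both libraries of that group together. These limits and the confidence intervals of ratios (95%, exact binomial) cover counting error only, because reads without molecular identifiers are not independent molecules.

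The 9491726 distinct sequences of the 4 libraries were placed by exact match on the TAIR10.1 genome, with both organelles, and on its spliced transcripts, with CCA added to tRNAs (Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, Numba 0.67.0; an index of 16 bases and at most 5000 places per read). In a check, 60 of 60 sequences drawn at random had the same number of places in a direct search. Reads placed on the genome were 79.6%, 80.8%, 80.8% and 80.4% of the libraries, and reads found in spliced transcripts alone were at most 0.315%. Each read was given 1 RNA class, the first that applied in a fixed order that begins with rRNA and tRNA and ends with intergenic sequence. A locus is a gene on its sense or antisense strand, taken at the midpoint of the read, and reads with several places were shared equally among them. The annotation holds the nuclear 18S and 5.8S rRNAs. The start of 25S rRNA came from a fixed sequence and its end from the pile of read 3' ends, and 5S rRNA came from BLAST+ 2.17.0 matches of at least 110 nt and 90% identity, at 242 places. rRNAs were divided into segments of 50 nt by the 5' end of the read. Mature miRNAs were counted as reads equal to one of 350 annotated mature sequences. Unplaced reads of 30 nt or more were compared with the rRNAs by BLAST+ over at least 25 nt. No annotation of transposable elements was present in the reference, so that list was not analysed.

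DEX was compared with mock by the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3, TMM scaling, filterByExpr, limma 3.58.1 beneath it) for loci, mature miRNAs, rRNA segments and distinct sequences with at least 15 counts over the 4 libraries. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each family, with a threshold of 0.05. The log2 changes and their standard errors (SE) come from these fits and are relative to the TMM scaling, whereas RPM values are relative to the total reads. For shares of reads, an exact two-sided permutation test was used (SciPy 1.17.1). With 2 libraries against 2 there are 6 arrangements, and the smallest p it can give is 0.333. The estimated biological coefficient of variation was 0.0918 for loci, 0.193 for miRNAs, 0.175 for sequences and 0.0648 for rRNA segments. In tests on simulated data with the same 4 libraries, 71.6% of loci changed by a log2 of 1 and 95.7% of those changed by a log2 of 2 were called, with 5 false calls. For miRNAs 3 of 10 and 10 of 10 were called, and for sequences 8.33% and 69.4%, with 200 of 107973 simulated as changed.

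The genes to name were chosen by a rule fixed before the data were examined, as were the gene lists, the tests and the alternatives, apart from the alternatives said to be chosen after seeing the data. Among loci past the threshold with a mean of at least 5 RPM and libraries that did not overlap, the 12 largest rises and the 12 largest falls were chosen, and 11 of these falls are described. For miRNAs the 12 largest changes in each direction and the 6 most abundant were named. For rRNA the 6 segments with the largest fold change and the 3 with the most reads were named. For sequences the 3 largest changes in each direction with a mean of at least 20 RPM were named. WUS, CLV3, each trans-acting siRNA (TAS) locus and each rRNA were always named. The 15 lists with at least 2 measured members were tested with camera of limma, at its preset correlation and with an estimated correlation, and with fry. Counts are also given adjusted over the list alone.

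The alternatives were DESeq2 1.42.0 with its own size factors, those size factors in edgeR, total library size without TMM, library sizes without rRNA reads, no filter on low counts, the replicate number as a block, each library left out in turn, reads of 18 to 28 nt, reads with 1 place, both strands summed, 100-nt segments, miRNAs matched by their 5' end, and other denominators for the shares. Chosen after seeing the data were a crossed pairing of the replicate block, a fit without loci that hold mostly rRNA, tRNA, snRNA or snoRNA reads, and the gene lists with each library left out. Apart from the replicate number, no label pairs a mock with a DEX library. Over 13254 loci the deviations of replicate 1 in mock and in DEX had a correlation of -0.12, so the block may model a pairing that is not there. Groups of 2 libraries are too few for other splits of the samples. The planned change of pseudocount was not run because the files hold counts. Figures were drawn with matplotlib 3.10.9.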

Results

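Small RNAs of 16 to 50 nt were sequenced from Arabidopsis shoot apices 2 days after a mock treatment or after DEX, which lets the WUS-GR fusion enter the nucleus. The purpose given for the series was to follow RNA degradation induced by WUS, the transcription factor that maintains the stem cells of the shoot meristem. There were 2 libraries per group. Mock replicates 1 and 2 held 10015234 and 10277955 reads, and DEX replicates 1 and 2 held 10048885 and 11171446 reads. Values are means ± SD with n = 2 libraries per group, and RPM is reads-per-million of all reads in the library. For protein-coding genes a rise or fall is one of reads of 16 to 50 nt. Levels of whole mRNAs were not measured, so more or fewer such reads need not mean more or less mRNA. The first principal component of the loci held 55.1% of the variance and separated DEX from mock.

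Fragments of ribosomal RNA took a larger share of the small RNAs after DEX. Nuclear rRNA made up 27.4% ± 0.770 of all reads in mock and 35.2% ± 1.11 in DEX, a difference of 7.88 percentage points. Plastid rRNA went from 1.99% ± 0.0836 to 3.21% ± 0.133. Most other classes took a smaller share: intergenic reads went from 22.1% ± 0.467 to 18.5% ± 1.03, miRNA reads from 4.16% ± 0.0425 to 3.33% ± 0.201, and TAS reads from 0.370% ± 0.0207 to 0.270% ± 0.00910. Sense reads of nuclear protein-coding genes, 48.7% of them 24 nt long in mock, went from 4.13% ± 0.0627 to 3.37% ± 0.191. Plastid reads other than rRNA and tRNA went from 0.820% ± 0.0399 to 0.429% ± 0.0130. Each of these differences was larger than the SD of either group. The exact permutation test gave p = 0.333 for each, the smallest that 2 libraries against 2 allow. Among reads other than rRNA most of these falls were smaller: intergenic reads were at 31.4% and 30.3%, miRNA reads at 5.91% and 5.44%, sense reads of protein-coding genes at 5.87% and 5.51%, TAS reads at 0.526% and 0.442%, and the other plastid reads at 1.17% and 0.702%. Counted over distinct sequences in place of reads, the difference in nuclear rRNA was 0.41 percentage points.

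**Figure D1:**
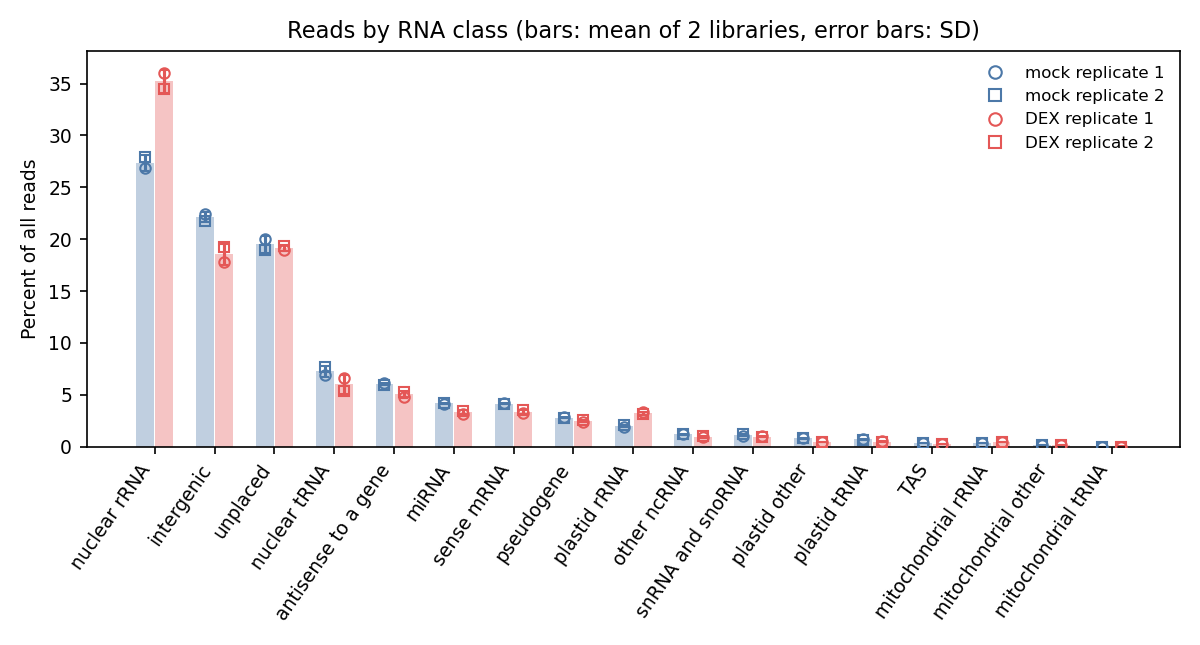
Bars give the mean percent of all reads in each RNA class for mock and DEX, with SD as error bars and each of the 4 libraries as a point. Nuclear rRNA goes from 27.4% to 35.2%, and intergenic reads go from 22.1% to 18.5%.

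Reads of 24 nt, the length of the siRNAs that guide DNA methylation in plants, made up 27.3% ± 0.775 of mock libraries and 23.3% ± 1.28 of DEX libraries. The difference was -4.05 percentage points, and among reads other than rRNA it was -1.77. Reads of 16 to 20 nt went the other way, from 16.3% ± 1.26 to 20.7% ± 1.61. Reads of 21 nt, the main length of miRNAs and trans-acting siRNAs, made up 7.63% in mock and 7.39% in DEX. The exact permutation p was 0.333 for the 24-nt share and for the 16 to 20 nt share. Within nuclear rRNA, reads of 16 to 20 nt made up 29.4% in mock and 33.7% in DEX, and reads of 29 to 50 nt 42.5% and 35.0%.

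**Figure D2:**
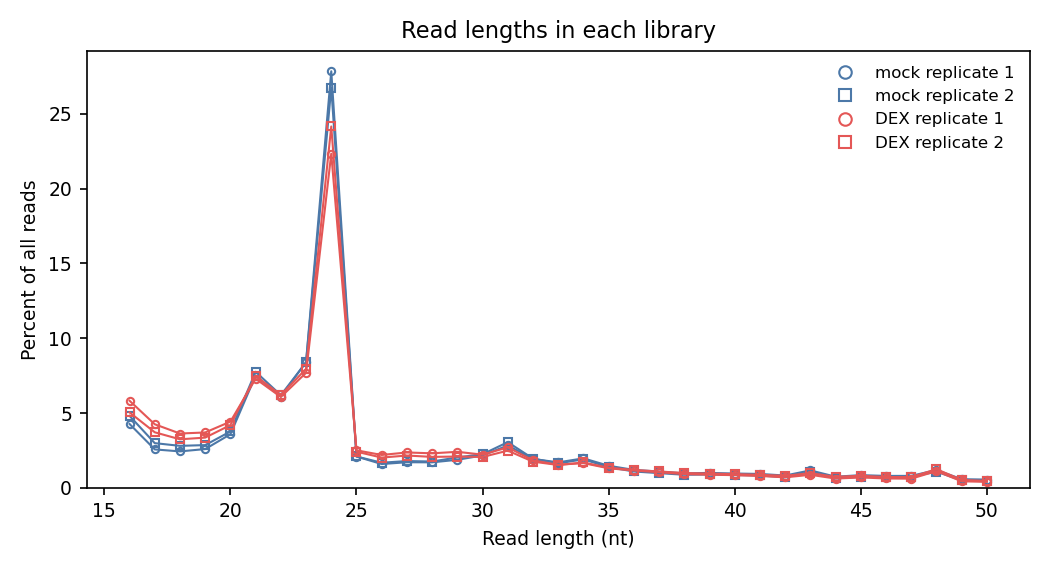
Lines give the percent of all reads (vertical axis) at each read length in nt (horizontal axis) for each of the 4 libraries. At 24 nt the mock libraries hold 27.9% and 26.8%, above the DEX libraries at 22.3% and 24.2%.

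The rise was uneven across the rRNAs. Sense reads of 25S rRNA, the large-subunit rRNA of cytoplasmic ribosomes (chromosome 3, 14200105 to 14203491, in TAIR10.1), went from 16.5% ± 0.761 of all reads to 25.1% ± 1.13, a ratio of 1.53. Reads of 18S rRNA, the small-subunit rRNA of the same transcript (14197677 to 14199484), went from 8.45% ± 0.0204 to 7.17% ± 0.0373. Counted as loci, 25S rRNA rose by a log2 change of 0.83 (SE 0.09, adjusted p = 0.00218), and 18S rRNA was at -0.05 (adjusted p = 0.91). The 5.8S and 5S rRNAs rose by 0.43 and 0.58 (adjusted p = 0.0303 and 0.0219). With DESeq2 neither passed (adjusted p = 0.83 and 0.20), nor did either pass without mock replicate 1 (0.32 and 0.27) or without mock replicate 2 (0.37 and 0.15). With the replicate number as a block, their adjusted p-values were 0.34 and 0.11. The internal transcribed spacers, which are removed when the rRNAs mature, had log2 changes of -0.20 (ITS1) and -0.41 (ITS2), and neither passed (adjusted p = 0.50 and 0.21).

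The large rRNAs of both organelles rose. Plastid 23S rRNA rose by a log2 change of 1.06 (SE 0.10, adjusted p = 0.00148) and plastid 16S rRNA by 0.93 (SE 0.10, adjusted p = 0.00234). As shares of all reads they went from 1.05% ± 0.0461 to 1.86% ± 0.0939 and from 0.576% ± 0.0271 to 0.937% ± 0.0357. The small plastid rRNAs did not pass (log2 changes 0.13 for 4.5S and -0.08 for 5S). In mitochondria, 18S rRNA rose by 0.81 (adjusted p = 0.00517) and 26S rRNA by 0.59 (adjusted p = 0.0176), while 5S rRNA was at 0.13. Without mock replicate 1, plastid 16S (adjusted p = 0.055), mitochondrial 18S (0.095) and mitochondrial 26S (0.24) no longer passed. Without mock replicate 2, mitochondrial 18S (0.053) and 26S (0.15) did not pass, and 26S did not pass with DESeq2 (0.17) or with the replicate block (0.090).

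Along the rRNAs, the change differed from one 50-nt segment to the next, and 211 of 315 segments passed the test, 101 upward and 110 downward. These directions are relative to the other rRNA segments, since TMM was computed over rRNA alone. Relative to total reads, which moves the median log2 change by 0.47, 197 rose and 37 fell, and relative to reads other than rRNA, which moves it by 0.67, 226 rose and 17 fell. In 25S rRNA 32 segments rose and 18 fell of 68 (54 and 6 relative to total reads). In 18S rRNA 32 of 36 fell and none rose, also at an unadjusted p under 0.05 and by DESeq2, which were likewise scaled over rRNA segments. Relative to total reads 6 rose and 16 fell, and relative to reads other than rRNA 10 rose and 11 fell. In plastid 23S rRNA 30 rose and 9 fell of 56 (46 and 1), and in plastid 16S rRNA 16 rose and 3 fell of 30 (26 and 0).

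The largest rise was at nt 1151 to 1200 of plastid 23S rRNA (plastid genome 105841 to 105890), from 622 ± 31.1 to 3172 ± 132 RPM, 5.10-fold. Within 25S rRNA, nt 1601 to 1650 went from 1594 ± 35.5 to 6743 ± 614 RPM and nt 1101 to 1150 from 2393 ± 91.5 to 9468 ± 720 RPM, and both rose (log2 changes 1.62 and 1.53). The largest falls were in ITS1 at nt 101 to 150 (log2 change -1.43), in ITS2 at nt 51 to 100 (-1.32) and in 18S rRNA at nt 451 to 500 (-1.31), where reads went from 3009 ± 218 to 1666 ± 101 RPM. The segment with the most reads, 25S nt 101 to 150, rose from 13652 ± 2199 to 23530 ± 2923 RPM (log2 change 0.33, adjusted p = 0.041), but not with the replicate block (0.11) or without mock replicate 1 (0.29). The first 50 nt of 5.8S rRNA were at 8439 and 11347 RPM (log2 change -0.03, adjusted p = 0.71). The 3' end of 25S rRNA, nt 3351 to 3387, was at 8445 and 7872 RPM and fell by 0.56 on the log2 scale, while relative to reads other than rRNA its log2 change was 0.10.

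**Figure D3:**
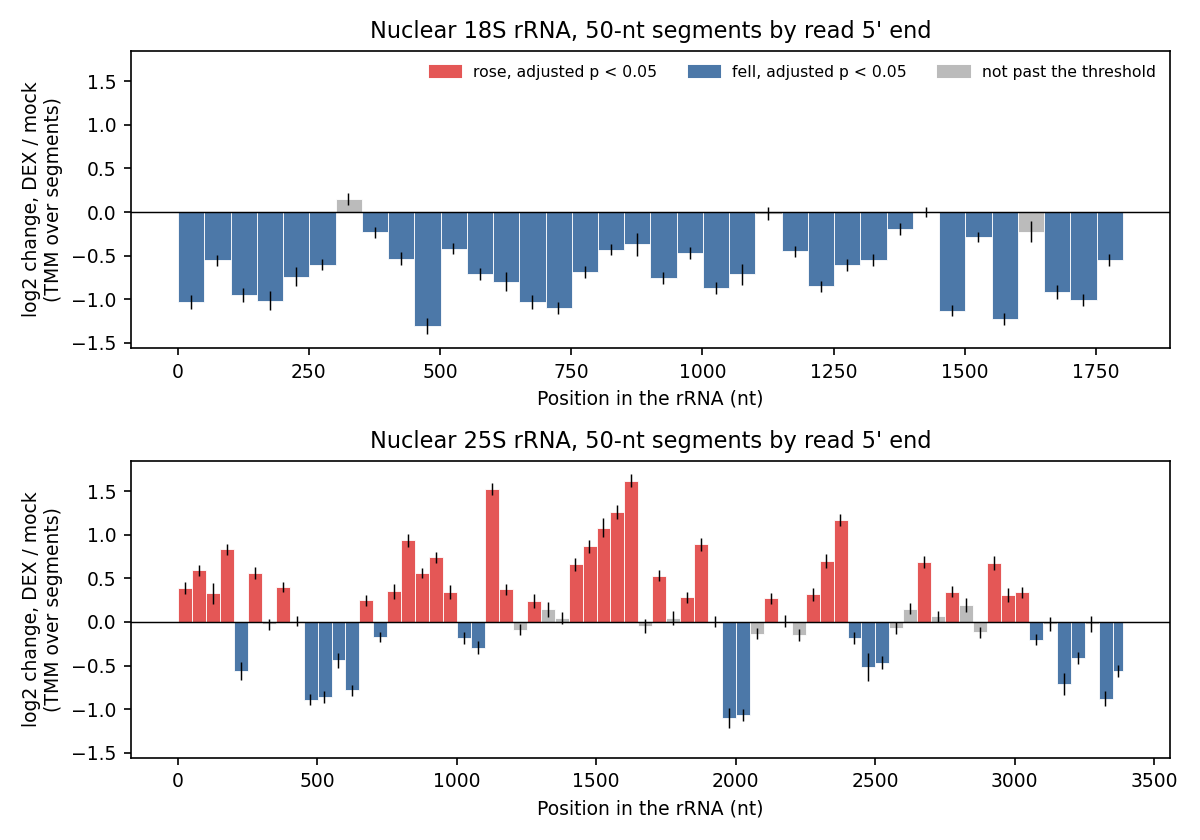
Points give the log2 change, DEX against mock, of each 50-nt segment along nuclear 18S and 25S rRNA (horizontal axis, nt from the 5' end), with SE as error bars and TMM scaling over the segments. In 18S rRNA 32 of 36 segments fell, and in 25S rRNA 32 rose and 18 fell. Relative to total reads 6 rose and 16 fell in 18S rRNA, and 54 rose and 6 fell in 25S rRNA. Relative to reads other than rRNA 10 rose and 11 fell in 18S rRNA, and 57 rose and 3 fell in 25S rRNA.

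Across the genome, 381 of 13254 loci changed, 125 upward and the others downward. Loci that hold mostly 24-nt reads made up 9522 of the loci tested and 131 of the calls, 125 of them downward. Their median log2 change was 0.02. As most of the loci tested, they weigh heavily in the TMM scaling, so a median near 0 does not show an unchanged level. Fragments of mRNAs of mixed length gave 55 rises and 73 falls of 1842, miRNA genes 12 and 16 of 276, and plastid and mitochondrial genes 1 and 19 of 173. Loci whose reads mostly also match rRNA, tRNA, snRNA or snoRNA gave 38 rises and 11 falls of 1022. The count of loci changed, DEX against mock, was 116 without mock replicate 1, 216 without mock replicate 2 and 652 without DEX replicate 1. DESeq2 gave 128, and total library size, which moves the median log2 change by -0.19, gave 707.

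Of the 12 largest rises, 4 came mostly from reads with 1 place in the genome. Antisense reads of SRF5 (AT1G78980, chromosome 1, 29707625 to 29711421), a receptor-like kinase gene of the STRUBBELIG family, rose from 1.53 ± 0.516 to 16.8 ± 1.41 RPM (log2 change 3.64, SE 0.18, adjusted p = 6.94e-05). Of these reads 0% were of 21 nt, of 24 nt or longer than 28 nt, so they lack the main siRNA lengths. MIR167c (AT3G04765, chromosome 3, 1306622 to 1306781), one of the precursors of miR167, which targets the auxin response factors ARF6 and ARF8, rose from 1.52 ± 0.321 to 13.9 ± 0.557 RPM (3.37, SE 0.17, adjusted p = 6.94e-05). MIR868 (AT3G18827) rose from 5.11 ± 1.16 to 11.6 ± 1.66 RPM (1.36), and without mock replicate 1 it did not pass (adjusted p = 0.057). VSP1 (AT5G24780, chromosome 5, 8507590 to 8509201), a jasmonate-induced vegetative storage protein, rose from 8.68 ± 0.438 to 18.8 ± 1.53 RPM (1.31, adjusted p = 0.000897).

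The other 8 of the 12 hold mostly reads that also match structural RNAs, 87.1% of the reads or more. They are AT1G78200, a protein phosphatase 2C family gene (5.66 ± 1.08 to 46.9 ± 12.4 RPM, log2 change 3.24), antisense reads of the snoRNA gene AT5G06305 (2.42), GTF2H2, a subunit of the transcription factor TFIIH (2.02), antisense reads of AT1G48360 (1.93), MIS12, a kinetochore protein (1.68), antisense reads of AT5G50290 (1.54), IAR4, a pyruvate dehydrogenase subunit (1.33), and the snoRNA gene AT1G06673 (1.33). With only reads that have 1 place, AT5G50290 antisense was at 0.15 (adjusted p = 0.90) and AT1G06673 at -0.17 (adjusted p = 0.86). MIS12 did not pass without mock replicate 1 (adjusted p = 0.10).

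Of the 12 largest falls, 11 are described here. Sense fragments of DIN10, of the raffinose synthase family, fell from 10.5 ± 0.959 to 1.62 ± 0.745 RPM (log2 change -2.47, SE 0.22, adjusted p = 0.00092). BGAL1, a beta-galactosidase, went from 9.46 ± 0.0339 to 1.69 ± 0.140 RPM (-2.28), and RBCS3B, a small subunit of Rubisco, from 8.47 ± 0.263 to 1.61 ± 0.254 RPM (-2.20). MIR164c (chromosome 5, 9852674 to 9852775), a source of miR164, which targets the CUC boundary genes, went from 31.3 ± 4.82 to 5.68 ± 0.708 RPM (-2.26), and MIR391 from 332 ± 24.8 to 80.6 ± 23.9 RPM (-1.86). The self-incompatibility pseudogene PSEUDOSRKA (chromosome 4, 11383433 to 11387188) gave mostly 21-nt reads and fell on both strands, sense from 44.6 ± 1.48 to 11.5 ± 0.270 RPM (-1.76) and antisense from 23.2 ± 0.552 to 6.39 ± 0.588 RPM (-1.66). AT4G21366, a protein kinase family gene on the opposite strand within its interval, was lower as well (-1.92). At a place within AT4G21366, a read on its strand was counted for AT4G21366 and not as antisense to PSEUDOSRKA. However, few reads of these loci had 1 place. The loci may share reads through other places, so the fall of AT4G21366 may not be a separate one. In PSEUDOSRKA sense 2.4% of the reads had 1 place, in antisense 0.7%, and in AT4G21366 0.2%. The remaining 3 named falls held mostly 24-nt reads: AT1G13760 (-1.81), antisense reads of AT1G77100, a peroxidase gene (-1.56), and AT4G24974, of the self-incompatibility S1 family (-1.56).

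WUS sense reads, which come from the endogenous gene (AT2G17950, chromosome 2, 7808871 to 7810811) and from the transgene, did not pass the test. They were at 10.5 ± 1.45 RPM in mock and 11 ± 2.9 RPM in DEX (log2 change 0.28, SE 0.17, adjusted p = 0.60). CLV3, the stem cell peptide of the meristem, had counts of 0, 0, 0 and 1, so a difference was not detectable at this depth, where a count of 0 allows up to 0.30, 0.29 and 0.30 RPM. Of 16 shoot meristem genes, WUS and the corepressor gene TPL (-0.49) were measured, and neither passed, nor at an unadjusted p under 0.05 in edgeR or with DESeq2 (camera adjusted p = 0.91). Floral organ genes gave 2 measured members of 7, AP2 (-0.19) and PI (-1.06), and neither passed with edgeR or DESeq2, while 1 had an unadjusted p under 0.05 in edgeR (camera adjusted p = 0.27). Both pollen genes were below the filter.

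The measured trans-acting siRNA loci, whose 21-nt products come from transcripts cleaved by miR173 or miR390, were lower in RPM. However, none of 14 measured strands passed over all loci with edgeR, where 7 had an unadjusted p under 0.05, or with DESeq2. Relative to total reads 6 fell, and without either DEX replicate 1 fell. TAS1C sense reads were at 1169 ± 22.9 and 819 ± 65.1 RPM (log2 change -0.32, adjusted p = 0.18), and TAS2 sense reads at 1421 ± 154 and 1068 ± 32 RPM (-0.22). TAS1A (-0.16), TAS1B (-0.26), TAS3 (-0.33), TAS3b (-0.34) and TASIR-ARF (-0.50) sense reads were also below 0, as were all 7 antisense strands. Adjusted over the list alone, 6 fell. The list tested lower than other loci with camera (adjusted p = 8.50e-05), but not with an estimated correlation (adjusted p = 0.50). TAS4 had counts of 0, 0, 2 and 1 and was not tested. The MIR173 precursor, the source of the trigger of TAS1 and TAS2, fell from 624 ± 62.9 to 336 ± 67.6 RPM (log2 change -0.70). The phased-siRNA PPR genes, which are also sources of 21-nt siRNAs, gave 22 measured strands of 11 genes, and none passed over all loci or adjusted over the list alone, nor at an unadjusted p under 0.05 in edgeR or with DESeq2 (median log2 change -0.05, camera adjusted p = 0.63). Of them AT1G63130 sense reads were at 54.9 ± 4.56 and 43.2 ± 2.57 RPM.

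Of 79 plastid loci, 15 fell with edgeR and 75 had a negative log2 change, with a median of -0.43. Genes of the inverted repeat are present in 2 copies that share reads, and by gene symbol 14 of 72 fell and 69 were below 0 (median -0.45). At an unadjusted p under 0.05, 51 loci fell and none rose, and DESeq2 called 1 fall over all loci, against 21 at an unadjusted p. Sense fragments of psbA, the D1 protein of photosystem II, went from 347 ± 22.5 to 200 ± 5.99 RPM (log2 change -0.60, adjusted p = 0.0228), and those of rbcL, the large subunit of Rubisco, from 147 ± 8.82 to 73.1 ± 1.07 RPM (-0.81, adjusted p = 0.00797). Among 12 nuclear photosynthesis genes 4 fell with edgeR, 2 with DESeq2 and 2 without mock replicate 1. The 4 were RBCS3B, RBCS1B (3.90 ± 0.280 to 0.955 ± 0.338 RPM, -1.84), RCA, Rubisco activase (9.13 ± 1.77 to 2.85 ± 0.480 RPM, -1.49), and RBCS1A (13.2 ± 0.242 to 7.55 ± 0.298 RPM, -0.61). Adjusted over the list alone, 4 fell and 1, CAB1, a chlorophyll-binding protein, rose (log2 change 0.36, adjusted p over all loci = 0.20). The list was lower with camera (adjusted p = 0.000262), but not with an estimated correlation (adjusted p = 0.61).

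Ribosomal protein genes had a median log2 change of -0.33, and 2 of 113 measured members fell with edgeR, where 18 fell at an unadjusted p under 0.05. DESeq2 called none, with 5 at an unadjusted p. Without mock replicate 1 none passed, without mock replicate 2 or DEX replicate 2, 1 fell, without DEX replicate 1, 4 fell, and relative to total reads 6 fell. The 2 were emb2386, ribosomal protein L19e (5.08 ± 0.581 to 1.95 ± 0.345 RPM, -1.20), and AT2G31610, ribosomal protein S3 (-1.44). Adjusted over the list alone, 1 fell. Camera gave an adjusted p of 2.80e-06, and the adjusted p was 0.48 with an estimated correlation and 0.19 with reads of 18 to 28 nt. The rRNA list went up, with 9 of 16 loci rising, 6 with DESeq2 or with the replicate block, 3 without mock replicate 1 and 5 without mock replicate 2 (camera adjusted p = 8.56e-08, adjusted p = 0.61 with an estimated correlation); adjusted over the list alone, 9 rose and 1 fell. Plastid 16S and 23S rRNA are present in 2 copies that share their reads, so 7 distinct rRNAs rose, and the list test counts each copy. Nucleolar and ribosome biogenesis genes, 3 measured of 6, did not pass, with NUC-L1 at 0.07, FIB1 at 0.02 and NOP56 at -0.07, also at an unadjusted p under 0.05 in edgeR and with DESeq2 (camera adjusted p = 0.91). Of 13 measured methyltransferase genes none passed over all loci with edgeR or DESeq2, and 1, AT4G26460 (-1.16), had an unadjusted p under 0.05 and fell adjusted over the list alone (camera adjusted p = 0.14).

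Of 610 tRNA genes 1 fell with edgeR, AT2G05315 (log2 change -0.84), and none adjusted over the list alone or with DESeq2. At an unadjusted p under 0.05 in edgeR, 17 rose and 115 fell. The count moved with single libraries, read length and scaling: 133 fell without DEX replicate 1, 26 rose without DEX replicate 2, 19 rose and 7 fell with reads of 18 to 28 nt, none changed without either mock replicate, and 90 fell relative to total reads. The most abundant, AT2G27850, was at 1165 ± 16.9 and 869 ± 3.36 RPM (-0.23). Copies of a tRNA gene share reads, as in a tRNA-Asp fragment placed on 23 genes. These counts and the list test therefore do not rest on independent members (estimated correlation 0.67). Camera placed the tRNA list lower (adjusted p = 0.00369), but not with an estimated correlation (adjusted p = 0.86), and it placed it higher with reads of 18 to 28 nt (adjusted p = 3.60e-07) or without DEX replicate 2 (0.000874). Without mock replicate 2 it was also placed higher but did not pass (adjusted p = 0.76). Of 261 snoRNA genes, which guide rRNA modification, 4 rose and 6 fell with edgeR (5 and 7 adjusted over the list alone), and DESeq2 called 1 rise. Without DEX replicate 2, 15 rose and 17 fell, without DEX replicate 1, 5 and 11, without either mock replicate 2 and 0, and relative to total reads 2 and 28. The risers were AT1G06673, AT5G04425 (0.98), AT1G04527 (0.63) and AT5G02675 (0.56). Camera gave an adjusted p of 0.0127 downward, and an adjusted p of 0.64 with an estimated correlation, 0.27 with reads of 18 to 28 nt, 0.76 without mock replicate 2 and 0.98 without DEX replicate 2. Of 41 spliceosomal snRNA genes U4.2 (24.4 ± 0.738 to 32.8 ± 0.811 RPM, 0.62) and U5.6 (15.5 ± 0.00455 to 23.7 ± 1.64 RPM, 0.81) rose, also adjusted over the list alone. DESeq2 called neither, with 2 rises at an unadjusted p under 0.05. With reads of 18 to 28 nt, 4 snRNA genes rose and 3 fell in edgeR. Without mock replicate 1 none passed in edgeR, without mock replicate 2 there was 1 rise, and relative to total reads 1 rose and 2 fell. The list did not pass with camera (adjusted p = 0.14), but it did without DEX replicate 2 (0.0154).

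In the defence list PR5, a thaumatin-like protein, rose from counts of 0 and 1 to 28 and 26, a ratio of 51.6 (95% interval 8.88 to 2077), and the salicylic acid receptor gene NPR1 did not pass (log2 change 0.21). These were the 2 measured members of 7, and 1 rose adjusted over the list alone. PR1 had counts of 0 and 0 in mock and 2 and 3 in DEX and was not tested. The list passed with camera (adjusted p = 0.00359), though not with an estimated correlation (adjusted p = 0.50), and with fry, which asks whether the members move one way (adjusted p = 0.0159). The call by fry was lost with the replicate block (adjusted p = 0.189) and with mock 1, mock 2, DEX 1 or DEX 2 left out (adjusted p = 0.212, 0.269, 0.131 and 0.173). The next lowest adjusted p of fry in that form was 0.127. Fry also has a mixed form, which asks whether members change in either direction. There the photosynthesis, TAS, ribosomal protein, snoRNA, miRNA and rRNA lists passed (adjusted p = 0.0327 each), as did the snRNA list (0.0368). The defence list did not pass in the mixed form (adjusted p = 0.124). With the replicate block each of these lists had an adjusted p of 0.2 or more in the mixed form. Of 15 lists tested, 8 passed with camera at its preset correlation and none with an estimated correlation in limma, where 1 had an unadjusted p under 0.05. Of 4 measured small RNA machinery genes none passed with edgeR or DESeq2, nor at an unadjusted p under 0.05, with AGO1, the main miRNA effector, at 0.02, DCL1, which cuts miRNA precursors, at -0.09, DCL4 at 0.60 and AGO4 at 0.87 (camera adjusted p = 0.27).

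Mature miRNAs changed in both directions: 32 of 145 passed, 15 upward and 17 downward. The largest rise was miR167c-5p (TAAGCTGCCAGCATGATCTTG, chromosome 3, 1306750 to 1306770), with counts of 1 and 5 in mock and 72 and 58 in DEX (0.293 to 6.18 RPM, log2 change 4.79, SE 0.56, adjusted p = 1.01e-13). Its partner strand miR167c-3p (2.49), miR5017-5p (2.40), miR868-5p (1.87), miR869.2 (1.76), miR5650 (1.61), miR5642a (1.43), miR859 (1.13), miR845b (1.13), miR780.1 (1.10) and miR845a (1.07) also rose. The most abundant of the rises named was miR780.2, from 114 ± 3.01 to 186 ± 3.76 RPM (1.16, adjusted p = 9.51e-05).

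Among miRNAs that fell, several were the less abundant strand of conserved families. Whether such strands fell more often than other miRNAs was not tested. Of miR157a-3p, from a family that targets SPL genes of phase change, reads went from 17.6 ± 4.57 to 0.826 ± 0.605 RPM (log2 change -3.97, SE 0.48, adjusted p = 2.90e-13). The others of this kind were miR160c-3p (-2.52), miR393a-3p (-2.44), miR156d-3p (-1.92), miR156a-3p (-1.83) and miR396b-3p, which went from 70.1 ± 4.77 to 16.0 ± 1.00 RPM (-1.69, adjusted p = 3.18e-06). Both strands of miR164c fell, 5p from 16.7 to 2.99 RPM (-2.04) and 3p from 12.8 to 1.93 RPM (-2.30). The 5p strand did not pass when reads were matched by their first 18 bases, with any 3' end (-0.56, adjusted p = 0.069). Such a match also counts any other miRNA with the same first 18 bases, so it does not single out the 3' ends of miR164c-5p. Both strands of miR391 fell as well, 3p from 11.7 to 1.72 RPM (-2.32), and so did miR397a (-1.75), which targets laccase genes. Counts of miR399c-5p were 17 and 11 in mock and 0 and 0 in DEX, at least 9.76-fold lower than in mock at 3 counts over both DEX libraries. miR846-5p had 21 counts in mock and 2 in DEX, a ratio of 11 (95% interval 2.68 to 96.6).

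The 6 most abundant miRNAs, which held 70.9% of mature miRNA reads, did not pass: miR159a (8757 ± 544 and 7232 ± 70.4 RPM, log2 change 0.18), miR158a-3p (0.16), miR167b (0.33), miR159b-3p (0.10), miR319a (0.25) and miR166c (-0.04). RPM values were lower in both DEX libraries than in both mock libraries for 85 of the 145. Relative to total reads, which moves the median log2 change by -0.41, 7 rose and 39 fell. Of 224 measured miRNA gene loci 12 rose and 16 fell (16 and 33 adjusted over the list alone, 7 and 4 with DESeq2), with MIR780 (0.80) and MIR839 (0.76) upward and MIR824, which targets AGL16, downward (-0.62). Without mock replicate 1, 4 rose and 4 fell, without mock replicate 2, 6 and 8, without DEX replicate 1, 13 and 28, without DEX replicate 2, 19 and 29, and relative to total reads 11 and 39. The list was lower with camera (adjusted p = 0.0484), but not with an estimated correlation (adjusted p = 0.61). Nor did it pass camera with the replicate block (adjusted p = 0.11), with total library size (0.054) or with any library left out. For mature miRNAs changed, DEX against mock, the replicate block in edgeR left 0 past the threshold. This compares with 29 at an unadjusted p under 0.05 and 26 with DESeq2 without a block. The block lost 24 of 24 named changes, whereas the crossed pairing of replicates lost 0 of 24. Of the named changes, 14 of 22 that could be tested did not pass without mock replicate 1. With DESeq2, miR167c-3p, miR5650, miR869.2, miR397a and miR846-5p did not pass, and miR397a and miR5650 did not pass with any library left out.

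**Figure D4:**
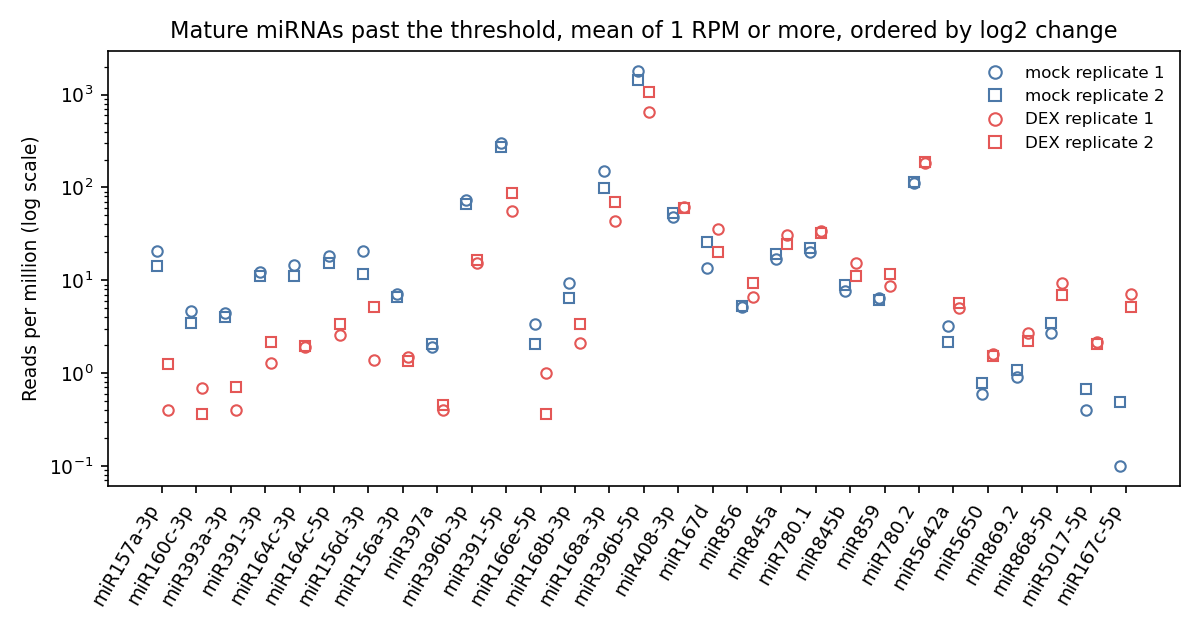
Points give the RPM (log axis) in each of the 4 libraries of the 29 miRNAs past the threshold with a mean of at least 1 RPM and reads in every library, ordered by log2 change. Relative to TMM, 15 are lower and 14 higher in DEX; relative to total reads, 39 of all 145 miRNAs fell and 7 rose.

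Single sequences showed where fragment ends lay. Of 107973 tested, 36669 changed, 22304 upward and 14365 downward, and nuclear rRNA gave 16930 of the rises and 6675 of the falls, plastid rRNA 2053 and 434. Sequences of plastid genes other than rRNA and tRNA gave 133 falls of 247, or 53.8%, against 13.3% of all sequences tested. Those of TAS loci gave 43 falls of 294, or 14.6%. TMM was computed over the sequences tested, 54652 of them nuclear rRNA, so rises and falls are relative to a set rich in rRNA. On that scale the median log2 change of TAS sequences was -0.53, against -0.28 for TAS strands as loci. The changes in 25S rRNA included CGGACCGGGCCTAAGTTCC (nt 172 to 190, chromosome 3, 14200276 to 14200294), which rose from 17.6 ± 0.513 to 485 ± 2.51 RPM (log2 change 4.67), and its form without the first base, GGACCGGGCCTAAGTTCC (3.20 ± 0.128 to 96.1 ± 16.5 RPM, 4.79). TGCCCACCCTGGAAACGGC (25S nt 1705 to 1723) rose from 1.63 to 45.6 RPM (4.69). Among falls, GCCGCACGCGCGCTACACTGATGT of 18S rRNA (nt 1461 to 1484) went from 116 ± 12 to 14 ± 0.684 RPM (-3.15), and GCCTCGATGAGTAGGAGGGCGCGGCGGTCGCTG of 25S rRNA (nt 1368 to 1400) from 36.6 to 4.54 RPM (-3.12). The plastid tRNA sequence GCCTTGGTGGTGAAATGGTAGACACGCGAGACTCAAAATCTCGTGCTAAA was at 99.8, 7.01, 5.17 and 7.52 RPM (-3.18), so mock replicate 1 decides it, and without that library the log2 change was -0.22 (adjusted p = 0.72). These 6 are the leaders among placed sequences. The 3 largest rises (log2 changes 6.19 to 7.84) and falls (-8.48 to -7.44) had no place in the genome, and their sequences are not given. The count of distinct sequences changed, DEX against mock, was 18199 with DESeq2 and 16816 without DEX replicate 2.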

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

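The tests reported here were chosen only after the result was seen, except the test of the gel size range, which was written before.

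Reads of 30 nt or more that match no place in the genome enter the report's shares and the test of distinct sequences, but not its comparisons of loci and rRNAs, and some resemble organelle rRNA at under 93% identity. Such reads resembling mitochondrial 26S rRNA were at 1994 ± 233 RPM in mock and 2558 ± 244 RPM in DEX (n = 2 libraries each), above the level in the mock samples. Those resembling mitochondrial 18S rRNA were at 871 ± 73.4 and 1178 ± 111 RPM. Those resembling plastid 16S rRNA were at 1928 ± 136 and 2150 ± 134 RPM. Those resembling plastid 23S rRNA went the other way, at 1038 ± 79.2 RPM in mock and 819 ± 50.2 RPM in DEX.

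After DEX, 25S rRNA reads took a larger share of the libraries and 18S rRNA reads a smaller one. First bases moved 0.115 times as much in 24-nt intergenic reads as in nuclear rRNA reads. The range over pairs of 1 mock and 1 DEX library was 0.0999 to 0.243. This argues against a preference of adapter ligation for first bases that acts alike on all reads. It cannot decide on one that acts on rRNA fragments and not on siRNAs, and ligation at the 3' end was not tested. The log2 change of 25S less that of 18S stayed in each of 3 length ranges, the smallest being 0.74, with 0.594 in the lowest pair. A different range of sizes taken from the gel thus cannot alone account for that difference. The change of each rRNA did vary with length. From 16 to 20 nt to 29 to 50 nt it went from -0.002 to -0.39 for 18S and from 0.74 to 0.36 for 25S. What stays open is a part of the gel range in each change and a ligation preference limited to rRNA fragments. As a hypothesis, breakdown that acts unevenly on rRNA after DEX stays open too. The design cannot assign such breakdown to WUS or to DEX itself.

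Chloroplast 16S and 23S rRNA rose while other chloroplast RNAs were lower. Less leaf tissue in the DEX samples may account for the latter, but this stays open, since the nuclear photosynthesis genes had a median log2 change 0.745 times that of the plastid genes (-0.32 and -0.43), with 10 of 12 below 0, and the ratio ran from 0.264 to 1.42 over pairs of libraries. Reads from bacteria may account for part of the rRNA rise, and no bacterial reference was at hand to assign reads to an organism. Unplaced divergent reads of 30 nt or more that resemble small-subunit rRNA of either organelle rose by a log2 of 0.25. Relative to exact plastid 16S reads of that length, which rose by 0.36, the change was -0.11 (-0.247 to 0.0294 over pairs). The 0.25 pools a log2 change of 0.16 in reads like plastid 16S and 0.44 in reads like mitochondrial 18S rRNA. Exact plastid 16S reads of all lengths rose by 0.70 in RPM, so this compares only part of the rise. Divergent reads that resemble large-subunit rRNA changed by -0.26 relative to exact plastid 23S reads (-0.476 to -0.0441). That divergent set pools a log2 change of -0.34 in reads like plastid 23S and 0.36 in reads like mitochondrial 26S rRNA. A change in how chloroplast rRNA is broken down after DEX was not tested and stays open too.

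The 24-nt reads took a smaller share after DEX. The larger share of rRNA reads may account for most of it, since among reads other than rRNA the log2 change of the 24-nt share was 0.303 times that among all reads (-0.07 and -0.23; ratio 0.061 to 0.417 over pairs). Whether the remainder reflects the siRNA pathway was not tested.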

How the results depend on the processing

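The crossed pairing of the replicate block, the loci without structural RNA reads and the gene lists with a library left out were chosen after seeing the data; the other alternatives were planned. Of the named genes, miRNAs, segments and sequences over the alternatives, 1202 of 1337 values kept their direction and side of the threshold, 94 lost the call, 39 gained one and 2 turned. Of 145 list values 123 did, of 169 shares 115 did, and 47 of 63 counts lay within 1.5 times the reported one. Where a group was left with 1 library, that library is assumed to vary like the others. The cause of a change was not tested unless a reason is given.

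For loci changed, DEX against mock (381), DESeq2 gave 128, total library size 707 (106 rose, 601 fell), no filter 725 of 50441 tested, crossed pairing 864, and leaving out each library 116 (without mock replicate 1) to 652 (without DEX replicate 1). For mature miRNAs changed, DEX against mock (32), the replicate block gave 0 in edgeR, with 29 at an unadjusted p under 0.05 and 26 by DESeq2; leaving out each library gave 11 (without mock 1) to 31. For distinct sequences changed, DEX against mock (36669), DESeq2 gave 18199, reads of 18 to 28 nt 18316 (of 65860 tested), and leaving out each library 16816 (without DEX 2) to 27812. For rRNA segments changed, DEX against mock (211), 100-nt segments gave 117, of fewer tested, and leaving out each library 173 to 216. For gene lists, DEX against mock (8 of 15), reads of 18 to 28 nt gave 5 of 12, the estimated correlation 0, with 1 at an unadjusted p under 0.05, and leaving out each library 5 (without mock 2) to 7.

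For RNA class shares, DEX against mock (nuclear rRNA, 7.88 points), distinct sequences gave 0.41 and leaving out each library 7.09 to 8.66; reads other than rRNA give no value. For read length shares, DEX against mock (24 nt, -4.05 points), distinct sequences gave -1.18, reads other than rRNA -1.77, and leaving out each library -4.96 to -3.15. Values that turned were the tRNA list (adjusted p 3.60e-07 with 18 to 28 nt, 0.764 without mock 2, 0.000874 without DEX 2; 2.42e-20, not turned, without DEX 1), AT1G06673 (-0.17 with reads of 1 place), 25S rRNA 3351-3387 (0.10 with library sizes without rRNA), and these shares in points. Over distinct sequences: other mitochondrial reads 0.0103, nuclear tRNA 0.0403, pseudogenes 0.105, snRNA and snoRNA 0.0209, 21 nt 0.164, 31 nt 0.0579. Among reads other than rRNA: other mitochondrial 0.00701, pseudogenes 0.0935, snRNA and snoRNA 0.000891. Nuclear tRNA was 0.123 with 18 to 28 nt, and the mitochondrial other share, difference in percentage points, was 0.0301 with reads shared among classes. At this depth the simulated calls found 3 of 10 miRNAs changed by a log2 of 1, so miRNA changes of that size may often be missed. For sequences they found 8.33%, but only 200 of 107973 were simulated as changed. In the data 22304 rose and 14365 fell. The adjusted threshold was thus stricter in the simulation, and 8.33% does not give the rate for the data.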

Other observations

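The genes named in this section, both rises and falls, and the tRNA fragments were chosen only after their values were seen. The test of 3' ends was written before its result was seen.

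Among mRNA fragments past the threshold over all loci, those of genes of several functions rose. LOX2, a lipoxygenase of jasmonate synthesis, rose from 5.51 ± 0.596 to 11.5 ± 0.608 RPM (n = 2 libraries each, log2 change 1.25, adjusted p = 0.00218). Fragments of the jasmonate regulators MYC2 (2.12 to 4.36 RPM, 1.24) and JAZ1 (1.38 to 3.07 RPM, 1.33) and of the storage protein VSP2 (5.48 to 10.6 RPM, 1.15) rose too. TAT3, a tyrosine aminotransferase, had no reads in mock and 18 and 28 in DEX, at least 14.7-fold higher at 3 counts over both mock libraries, and FMO1, which makes N-hydroxypipecolic acid, was at least 9.24-fold higher by the same measure. The transporter gene ABCG40 went from 0.393 to 6.60 RPM (4.23), and the transcription factor gene WRKY70 from 0.644 to 3.18 RPM (2.49). CYP71A13, of camalexin synthesis, had 3 counts in mock and 43 in DEX, a ratio of 13.7 (95% interval 4.39 to 69.1). No enrichment test was run on these genes, and levels of their whole mRNAs were not measured.

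Among fragments that fell, the peroxidase gene PRXCB went from 4.29 to 0.189 RPM (log2 change -4.24) and CA1, a chloroplast carbonic anhydrase, from 3.06 to 0.234 RPM (-3.44). The sucrose transporter gene SUC1 had 56 counts in mock and 2 in DEX, a ratio of 29.3 (95% interval 7.74 to 248). GSTF9, a glutathione transferase, went from 6.90 to 1.57 RPM (-1.95) and PEN3, a transporter of pathogen defence, from 16.5 to 7.26 RPM (-0.99). The myrosinase genes TGG1 (-1.01) and TGG2 (-1.37) and PEN2 (-1.63), which also act in defence, fell too. Of the 5' fragments of tRNA-Asp, whose reads are shared by 23 genes, the 31-nt form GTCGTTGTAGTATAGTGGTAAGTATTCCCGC was at 8109 ± 1081 and 5947 ± 789 RPM, and the 28-nt form at 632 ± 104 and 1560 ± 505 RPM. The 29-nt form, at 3256 ± 631 and 4571 ± 1251 RPM, and the 30-nt form, at 1743 ± 240 and 1664 ± 234 RPM, had libraries that overlapped.

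Fragments of nuclear rRNA, plastid rRNA and long mRNA reads ended in C more often in DEX (21.6% to 26.3% of nuclear rRNA reads). Reads ending in G were also higher in nuclear, plastid and mitochondrial rRNA, by 3.19, 1.67 and 1.04 percentage points, and reads ending in A or T lower. The hypothesis that cuts after C are more frequent in the DEX samples was tested on mitochondrial rRNA, which had not been looked at. Its share of reads ending in C was 4.12 percentage points higher in DEX (3.38 to 4.85 over pairs of libraries; 21% to 25.1%), while 24-nt intergenic reads moved by 0.00744 points. This meets what the hypothesis needs, but it does not account for the G ends, and the shift may instead reflect another step that acts on fragments and not on siRNAs. No nuclease was tested, and DEX itself stays confounded with WUS.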
